A study of Homo sapiens with 10 samples.

How the data were processed

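RNA was measured in cultured normal human skin fibroblasts with a 1-colour Affymetrix expression array of 22277 probe sets. The cells grew in medium with 10% serum, were moved to serum-free medium, and were then stimulated, per the labels' protocols; those stimulated for 1 h had 47 h without serum before it, those stimulated for 24 h had 24 h, and the control had 48 h untreated. RNA was extracted on columns, labelled with biotin and hybridised by the manufacturer's protocol, per the labels' protocols. The values the authors deposited are signal intensity per probe set on a linear scale, made with MAS5 in GCOS, per the submitters' processing notes; the software versions are not given in the sources used here. The trimmed mean that leaves out 2% of the probe sets at each end was 100.03 on all 10 arrays, so the deposited intensity had already been scaled to 1 target, and it was not scaled again. Detection calls were not used here. The median signal was 17.7 to 19.8 per array, and for such arrays only their number, 2 per group, states the precision.

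Samples were assigned to the 5 groups from their titles, which also give the replicate number. The series describes 2 biological replicates, and p-values measure the spread between these arrays. Probe sets were named from a table of the platform's annotation, which can be old: 19064 had 1 gene symbol, 1043 several and 2108 none, and 62 were control probe sets. Of the first, 19052 were found by Entrez identifier in the RefSeq gene table of assembly GRCh38.p14, which was used for names only, and 0 symbols differed. Probe sets with several or no symbols were left unnamed and untested.

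Values were transformed as log2(signal + 2.05), where 2.05 is the 20th percentile of all deposited signals, so a log2 change understates the change of dim genes. Probe sets had to exceed the 40th percentile of the array, a signal of 7.96 to 10.6, on at least 2 arrays; 13109 with 1 symbol did, and the probe set with the highest mean stood for each of 8576 genes. The 5 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, 5 residual degrees of freedom), and 9 comparisons were tested with Benjamini-Hochberg adjustment over the genes of each, at an adjusted p of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, over the lists with at least 5 tested genes. An adjusted p of a list is from camera and is adjusted over the lists of 1 comparison.

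The design, the alternatives, 29 gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison with the control, the 12 largest increases and the 8 largest decreases among called genes whose stimulated arrays both lay on 1 side of both control arrays, up to 4 members of each list by adjusted p (also between the factors), and a set of genes named in every case, among them FOXO1, FOXO3, FOXO4, PDGFRA, PDGFRB, FGFR1, FOS, EGR1, MYC and CCND1. It took 8 genes in each direction between factors and for the interaction, and 4 in each direction between times. Genes outside it are named where a count was small or in the closing observations, and were chosen after their values were seen. Of 142 gene and comparison pairs with another measured probe set, 3 had one of opposite sign, for PDGFRA, NOP16 and NR4A1, and 0 of those passed the threshold. In 80 pairs another probe set did not pass, and in 21 of these it also showed under 0.5 times the change.

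Without detection calls, background was taken from 27 probe sets for bacterial transcripts, whose highest signal was 3.98 to 7.66 per array. This rule was chosen after seeing the data. A gene at or under that level on both arrays of a group has only a bound there: the fold is given as at least the mean log2 signal of the brighter group over the mean of the higher of the gene's signal and the background level, and no fold is given where it is under 1.

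Replicate numbers are shared by all groups. Deviations of the same-numbered arrays from their group means correlated across genes in each of the 10 pairs of groups, at 0.157 to 0.335, and the second principal component separated the numbers, so the numbers were taken to pair the arrays. The fit with the replicate number as a block (4 residual degrees of freedom) is given beside each count. The replicate sets also differed in 3′ to 5′ ratios of control probe sets, which for ACTB were 1.25 to 1.32 and 1.44 to 1.56 and for GAPDH 0.950 to 1.01 and 1.01 to 1.09.

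The procedure was tested on simulated data. With 50 genes of each size changed in a simulated comparison of PDGF-BB at 24 h with the control over 8576 genes, 11.5% of changes of 0.5 (log2), 56.6% of 1, 89.2% of 2 and 96.9% of 3 were called in 20 simulations, with 7.20 false calls on average and 0 sign errors. In a simulated comparison of PDGF-BB at 1 h with the control over 8576 genes and no change, 0.2 genes were called on average. A shift of 0.5 in the mitosis list at b-FGF 24 h was called in 5 of 5 simulations, and 1 list was called over 5 simulations without change. The simulated genes and arrays varied independently, with no correlation between genes and no deviation shared by a replicate set. The simulations therefore cannot show how the preset correlation performs in these data.

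Alternatives covered quantile normalization, a common median, other pseudocounts and filters, probe sets averaged or tested singly, a minimum fold, the variance model, array weights, fits of only the groups compared, the replicate block, and leaving out each array. Genes of the Y chromosome and XIST entered the tests but are not named. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.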

Results

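Gene expression was measured in cultured normal human skin fibroblasts stimulated with platelet-derived growth factor BB (PDGF-BB) or with basic fibroblast growth factor (b-FGF, the product of FGF2), which are mitogens that act through receptor tyrosine kinases. There were 5 groups of 2 arrays each, described in the labels as biological replicates: an unstimulated control, PDGF-BB for 1 h, b-FGF for 1 h, PDGF-BB for 24 h and b-FGF for 24 h. PDGF-BB was given at 25 ng/ml, and b-FGF at 10 ng/ml together with heparin, a glycan that stabilises b-FGF, at 50 µg/ml. All cells had 48 h in serum-free medium in total, so that control and stimulated cells differed in the factor and not in the length of serum deprivation. No group received heparin without b-FGF, so a b-FGF value below is the value of b-FGF with heparin. Each array reported 22277 probe sets, of which 8576 genes entered the tests, and the number of arrays limits the precision. Values are given as mean signal ± SD of the 2 arrays of a group, and changes as log2 differences with their standard error (SE).

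The main division among the 10 arrays was between the 24 h stimulations and the rest. The first principal component, with 46.4% of the variance, separated the 4 arrays of 24 h stimulation from the 6 control and 1 h arrays. The second component, with 13.1%, separated replicate 1 from replicate 2 in each group. Pearson's r across genes was 0.971 to 0.976 between the arrays of one group, and 0.926 to 0.984 between arrays of different groups. The replicate sets also differed in a measure of RNA integrity and labelling, the 3′ to 5′ ratio of control probe sets: for ACTB it was 1.25 to 1.32 on the arrays of replicate 1 and 1.44 to 1.56 on those of replicate 2. Each replicate set held all 5 groups.

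**Figure D1:**
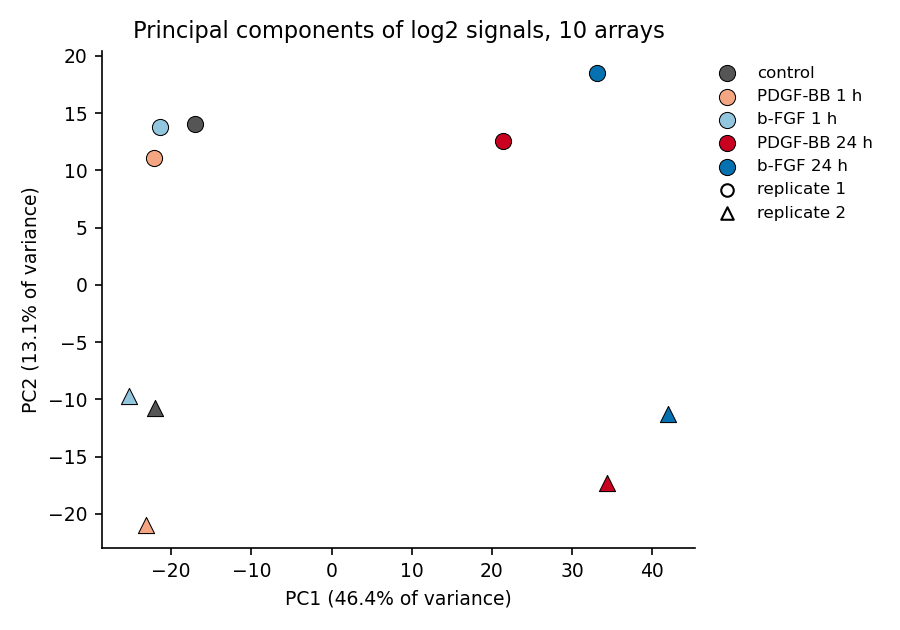
Principal components of the log2 signals of 8576 genes on 10 arrays, with the first component (46.4% of variance) on the x axis and the second (13.1%) on the y axis. Colours mark the 5 groups and symbols the replicate number; the 24 h arrays lie at the right, and replicate 1 lies above replicate 2 in every group.

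The median signal of each marker list of cells other than fibroblasts was close to background in all groups, though single members were well above it. The median signal of 18 leukocyte markers was 2.40 in the control and 3.61 after 24 h of PDGF-BB, with no member above 11.8, and that of 15 endothelial markers was 1.96 in the control with FLT1 highest at 101. Among 10 melanocyte markers the median was 3.16 and MITF was highest at 74.7, and among 16 keratinocyte markers the median was 2.22 and KRT10 was highest at 605. The 16 fibroblast markers had a median signal of 2086 in the control and 1781 after 24 h of b-FGF, with COL1A2 highest in each group.

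The first comparison asked which genes respond within 1 h of PDGF-BB. SOCS3, an inhibitor of JAK-STAT signalling, rose from 7.78 ± 7.66 to 240 ± 156 (SD, n = 2; log2 change 4.72 ± 0.80 SE, adjusted p = 0.0149), though another probe set for it, with a mean signal of 16.3, gave 2.14 and did not pass (adjusted p = 0.0674). CISH, of the same family, rose at least 17.7-fold from a control level at background. The nuclear receptor genes NR4A3 (at least 12.9-fold), NR4A1 (log2 change 3.29, and 1.01 and 1.77 by dimmer probe sets that did not pass) and NR4A2 (3.21) rose, as did the AP-1 family genes FOSB (at least 8.17-fold), ATF3 (3.71) and JUNB (2.89), the prostaglandin synthase gene PTGS2 (3.56), and the transcription factor genes NFIL3 (3.18), EGR3 (3.14) and IRF1 (2.80). IRF1 went from 39.3 ± 0.87 to 287 ± 33.5 signal units (SD, n = 2; adjusted p = 8.72e-06). In all, 65 genes passed the threshold, 64 higher and 1 lower, and 52 of them changed at least 2-fold. The single decrease was in PLK2, a polo-like kinase gene (log2 change -1.26 ± 0.24 SE, adjusted p = 0.0387).

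By gene list, 23 of 36 immediate early genes rose after 1 h of PDGF-BB and 1 fell, with a median log2 change of 1.08 over the list; adjusted over the list alone, 29 rose and 1 fell. The list call held with an estimated correlation (camera, adjusted p = 0.000682). FOS itself did not pass at this time (log2 change 0.08 ± 0.87 SE), while EGR1 (0.82) and MYC (0.89) did. Of 16 genes of the ERK feedback list, some of which restrain MAP kinase signalling, 4 rose: DUSP5 (2.04), DUSP1 (1.35), SPRY2 (1.54) and SPRY4 (1.23). When adjusted over the list alone, 6 rose and 1 fell (camera, adjusted p = 0.0251 with an estimated correlation). Among 20 cytokine and NF-κB genes, 5 rose, including IL6 (2.09), LIF (1.95) and IL11 (1.75), and 11 rose when adjusted over the list alone (adjusted p = 0.00364 with an estimated correlation). ID1 (2.69), ID3 (2.74) and KLF10 (1.77) rose among 22 genes of TGF-β and BMP response, with 5 when adjusted over the list alone (adjusted p = 0.0126 with an estimated correlation). The growth factor genes HBEGF (2.25), GDF15 (2.09) and VEGFA (1.16) rose among 22 ligand genes, with 4 when adjusted over the list alone, and the clock genes NFIL3 and BHLHE40 (2.64) among 13, with 3 when adjusted over the list alone. The last 2 lists passed with an estimated correlation (adjusted p = 0.0494 and 0.0429) but not with the replicate block added to it (adjusted p = 0.0786 and 0.0929). Lists of amino acid and ATF4 genes (median 0.06) and of interferon response (0.28) passed with the preset correlation, with adjusted p = 0.0207 and 5.17e-05, and not with an estimated one (adjusted p = 0.524 and 0.208); adjusted over the list alone they had 2 and 1 higher genes.

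With the replicate number as a block, PDGF-BB at 1 h gave 103 genes, 97 higher and 6 lower, which included the 65. The count was 42 without control replicate 2, 37 without PDGF-BB 1 h replicate 1 and 31 without PDGF-BB 1 h replicate 2.

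The matching question for b-FGF gave a smaller set with similar leading members. FOSB rose at least 4.88-fold and NR4A3 at least 4.35-fold from control levels at background, EGR3 rose from 20.2 ± 6.13 to 178 ± 6.36 (SD, n = 2; log2 change 3.05 ± 0.22 SE, adjusted p = 0.000174), and ATF3 (2.20), NR4A1 (2.04) and JUNB (1.91) followed. DUSP5 (1.87), a phosphatase that acts on ERK, IER3 (1.62), the RNA-destabilising factor gene ZFP36 (1.56), IER2 (1.44), SPRY2 (1.39) and TRIB1 (1.34) completed the 12 largest increases. MYC (1.03) and EGR1 (0.90) rose, and FOS did not pass (0.32 ± 0.87 SE). Altogether 23 genes rose, 19 of them at least 2-fold. No gene fell in limma's moderated test, in which 115 genes were lower and 123 higher at an unadjusted p under 0.05. Together these 238 genes were under 0.05 of the 8576 tested, the share expected if no gene changed.

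Of the 36 immediate early genes, 16 rose after 1 h of b-FGF, and 25 when adjusted over the list alone (camera, adjusted p = 0.000637 with an estimated correlation). From the ERK feedback list DUSP5, SPRY2 and DUSP1 (1.11) rose, and 6 genes when adjusted over the list alone (adjusted p = 0.0332 with an estimated correlation). The TGF-β and BMP list and the clock list passed with the preset correlation (adjusted p = 0.00352 and 0.00912) and not with an estimated one (adjusted p = 0.0998 and 0.128), with 3 and 2 genes higher over the list alone. The cytokine and NF-κB list did not pass (median log2 change -0.04, adjusted p = 0.0854); it did with the replicate block (0.0138), and not with the block and an estimated correlation (adjusted p = 0.222). FOXO1, FOXO3, FOXO4, PDGFRA, PDGFRB, FGFR1 and CCND1 did not pass at 1 h with either factor. With the replicate block, b-FGF at 1 h gave 39 genes, 38 higher and 1 lower, which included the 23. The count was 11 and 8 without control replicates 1 and 2, and 2 and 4 without b-FGF 1 h replicates 1 and 2.

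The direct comparison of the factors at 1 h found 8 genes, all higher with PDGF-BB. CISH had the largest fitted difference (log2 difference 3.99 ± 0.62 SE, adjusted p = 0.0485), with 96.4 ± 37.9 signal units after PDGF-BB and 4.82 ± 4.82 after b-FGF (SD, n = 2). The background level on those b-FGF arrays was 4.48 and 3.98, near that mean, so the size of the difference depends on the pseudocount. IRF1, an interferon-regulatory transcription factor gene, was at 287 ± 33.5 with PDGF-BB and at 31.5 ± 1.88 with b-FGF, where the control was at 39.3 ± 0.87 (difference 3.10 ± 0.18 SE, adjusted p = 1.38e-05). The other 6 were NFIL3 (2.01), ID1 (1.99), BHLHE40 (1.96), ID3 (1.69), ATF3 (1.51) and CCNL1 (1.14). In the same test 144 genes were lower and 259 higher with PDGF-BB at an unadjusted p under 0.05. These 403 genes were also under 0.05 of the 8576 tested, the share expected if no gene differed. SOCS3 was not among the 8, with 240 ± 156 signal units on the 2 PDGF-BB arrays.

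All 23 genes called with b-FGF at 1 h were also called with PDGF-BB, where independent lists of these sizes would share 0.172 genes. Of the 65 genes called with PDGF-BB, 63 changed in the same direction with b-FGF and 61 changed more with PDGF-BB, with a median log2 change of 1.73 against 0.87. These genes were selected for their PDGF-BB change; over the 23 genes called with b-FGF the medians were 1.73 with PDGF-BB and 1.34 with b-FGF, and 4 changed more with b-FGF. Across all 8576 genes, which are not independent replicates, the changes at 1 h correlated at r = 0.497 (Spearman 0.387). Groups without any change against the same controls gave r = 0.499 in simulation, and the covariance exceeded the simulated one by 0.00779. The controls were not split, since each factor would have kept 1 control array, so part of the overlap may come from the shared control arrays. Of the lists, the cytokine and NF-κB list (median difference 0.65, 1 gene past the threshold and 8 when adjusted over the list alone), the immediate early list (0.37, 1 gene, and 10 higher with 1 lower over the list alone) and the TGF-β and BMP list (0.12, 2 genes, 3 over the list alone) were higher with PDGF-BB. They passed with an estimated correlation (adjusted p = 0.0179, 0.0435 and 0.0435). With the replicate block added, the first still passed (0.0491) and the other two did not (adjusted p = 0.132 for each). Lists of FOXO, glycolysis, interferon and clock genes passed only with the preset correlation (adjusted p = 0.246, 0.323, 0.323 and 0.190 with an estimated correlation), and over the list alone had 1 gene lower, 1 higher, 1 higher and 2 higher. With the block, 34 genes differed, 33 higher with PDGF-BB. Leaving out any of the 4 arrays compared gave 4 genes.

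**Figure D2:**
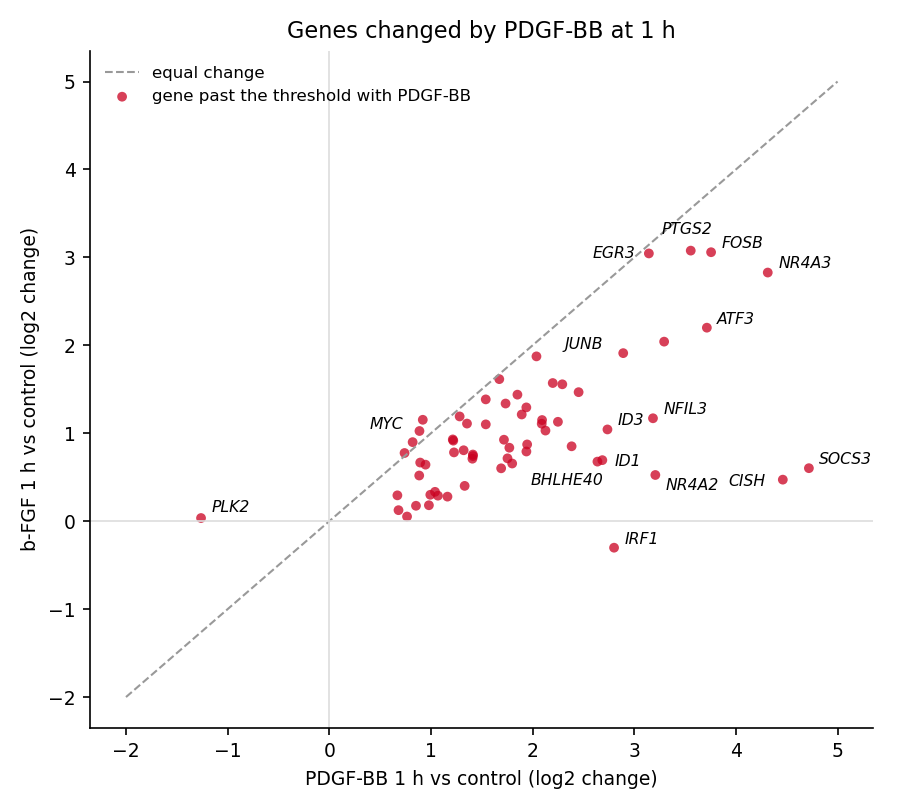
Log2 changes after 1 h of PDGF-BB (x axis) and of b-FGF (y axis) against the unstimulated control, for the 65 genes called with PDGF-BB at 1 h. Each point is the fitted value of 1 gene from 2 arrays per group, and the dashed line marks equal change; IRF1 lies at 2.80 with PDGF-BB and -0.30 with b-FGF, while EGR3 lies near the line at 3.14 and 3.05.

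After 24 h of PDGF-BB the response was broader, and 1201 of the 1226 genes called had not been called at 1 h. Of the early genes, 18 were higher at both times, where independent lists would share 4.27. Cell division genes rose: of 40 mitosis genes, 28 passed and all 40 had a change above 0, with a median of 1.55, and 35 rose when adjusted over the list alone. AURKA, a mitotic kinase gene, went from 90.6 ± 1.50 to 435 ± 54.6 (SD, n = 2; log2 change 2.23 ± 0.19 SE, adjusted p = 8.43e-05), and TPX2 (1.62), KIF20A (1.62) and CCNB1 (1.92) rose. Of 40 genes of the G1/S transition and DNA replication, 11 rose, 15 when adjusted over the list alone and 21 with the replicate block, among them CCNE2 (1.75), ORC6 (1.49), FEN1 (1.42) and CCND1 (0.87). Both lists passed camera with the preset correlation (adjusted p = 6.57e-20 and 3.67e-07), and neither did with an estimated correlation (adjusted p = 0.189 and 0.343).

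Lipid synthesis genes rose with PDGF-BB at 24 h. In the list of sterol synthesis and uptake 14 of 21 genes rose, 16 when adjusted over the list alone, with a median of 0.88, including DHCR7 (1.76) and EBP (1.78) of the late cholesterol pathway, FDPS (1.31) and INSIG1 (1.40). In the fatty acid list 7 of 14 rose, 9 over the list alone, including ELOVL6 (2.14), SCD (1.65), LPIN1 (1.63) and ACLY (0.89). Their adjusted p was 2.40e-10 and 4.44e-06 with the preset correlation, and adjusted p = 0.189 and 0.0944 with an estimated correlation.

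FOXO1, a transcription factor restrained by AKT signalling, fell from 27.4 ± 2.86 to 7.63 ± 0.76 after 24 h of PDGF-BB (SD, n = 2; log2 change -1.60 ± 0.31 SE, adjusted p = 0.00598). The background level on the PDGF-BB 24 h arrays was 6.62 and 6.72, so FOXO1 lay close to it there. Another FOXO1 probe set, with a mean signal of 5.10, gave -1.28 and did not pass. FOXO3 (-0.28, adjusted p = 0.307) and FOXO4 (-1.06, adjusted p = 0.135) did not pass. In the list of FOXO genes and their reported targets, 12 of 21 fell, 16 when adjusted over the list alone, with a median of -0.73, including the insulin receptor substrate gene IRS2 (-2.20), GABARAPL1 (-1.98) of autophagy, MXI1 (-1.76) and the CDK inhibitor gene CDKN1B (-1.32). The list passed with the preset correlation (adjusted p = 2.61e-09) and not with an estimated one (adjusted p = 0.0944). Of 17 genes of quiescence and growth arrest, 5 fell and 1 rose, 6 and 1 over the list alone, among them GAS1 (-1.70), SELENOP (-2.18), CDKN1C (-1.53) and SERPINF1 (-0.92), with adjusted p = 0.0125, and adjusted p = 0.189 with an estimated correlation.

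After 24 h of PDGF-BB, FABP3, a fatty acid binding protein gene, rose from 15.2 ± 0.76 to 188 ± 56.4 (SD, n = 2; log2 change 3.43 ± 0.27 SE, adjusted p = 5.34e-05), the hormone gene STC1 rose by 3.29 and the hepatocyte growth factor gene HGF by 2.53. Other probe sets for HGF gave 0.97 to 2.26, and only that at 2.26 passed. PTGS2 (2.93), G0S2 (2.77), CDCP1 (2.71), the hyaluronan synthase gene HAS2 (2.67) and PODXL (2.61) rose, and SPC25, ODF2, KIFC1 and ITPKA rose at least 6.17-fold, 4.71-fold, 3.35-fold and 3.30-fold from background. OLFM4 fell from 85.6 ± 4.31 to 5.07 ± 3.49, and the interferon-induced gene IFIT1 from 811 ± 19.9 to 64.2 ± 0.84 (SD, n = 2; log2 change -3.62 ± 0.12 SE, adjusted p = 4.60e-08). FOS (-3.58), IFIT2 (-3.08), the protocadherin gene PCDH8 (-2.99), CEMIP (-2.97), which acts in hyaluronan breakdown, and the aggrecanase gene ADAMTS5 (-2.97) fell, and the cadherin gene CDH6 fell at least 6.58-fold to background. Other probe sets for CDH6 gave smaller log2 changes of -1.66, -1.98 and -1.30, and only the first passed. EGR1 and MYC, raised at 1 h, were at -0.05 and 0.03 and did not pass.

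Of other lists at 24 h of PDGF-BB, ERK feedback had 7 of 16 genes higher and 2 lower, including ETV1 (1.66), DUSP6 (1.31) and SPRY4 (1.47) against DUSP1, which fell, and the unfolded protein list had 7 of 18 higher, 13 with the block, including SDF2L1 (1.50) and MANF (1.29). Glycolysis had 4 of 20 higher, 10 with the block (ENO1, 0.73), and ribosome biogenesis 3 of 24, 7 with the block (GAR1, 0.86). Collagen and matrix genes fell in 9 of 42 cases and rose in 2, with 15 and 4 under the block; PCOLCE (-0.78), FBLN5 (-0.73) and FBLN1 (-1.03) fell and TNC (1.12) rose. TGF-β and BMP response had 4 of 22 lower and 1 higher (ID2, -1.62; BAMBI, -1.97; SMAD6, -1.24; LTBP1, 1.07), and the fibroblast markers 4 of 16 lower and 1 higher (TWIST1, -1.21; FAP, -0.79; PRRX1, 1.08). Adjusted over the list alone, higher and lower members numbered 8 and 2 for ERK feedback, 9 and 0 for the unfolded protein list, 5 and 0 for glycolysis, 3 and 0 for ribosome biogenesis, 2 and 12 for collagen and matrix, 1 and 5 for TGF-β and BMP, and 1 and 6 for the fibroblast markers. All 7 lists passed camera with the preset correlation. None did with an estimated correlation, where in the order named the adjusted p = 0.151, 0.143, 0.189, 0.189, 0.189, 0.145 and 0.151.

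Lists that did not pass at 24 h of PDGF-BB included members that did. PHLDA1 (2.09) and KLF6 (1.31) rose and CCN2 (-0.87) and KLF4 (-0.87) fell among the immediate early genes (5 higher and 5 lower of 36). IFIT1, IFIT2 and IFIT3 (-1.77) fell among 23 interferon response genes, whose list had adjusted p = 0.0529 and, with the block, 0.0422 (adjusted p = 0.419 with the block and an estimated correlation). TNFAIP6 (1.75) rose with PTGS2 among the cytokine genes, XYLT1 (1.05), HMMR (2.15), HAS2 and TNFAIP6 among 10 hyaluronan and proteoglycan genes, where ITIH5 fell (-0.72) and whose list had adjusted p = 0.0517 and, with the block, 0.0252 (adjusted p = 0.205 with the block and an estimated correlation). PLAU (2.03), MMP1 (1.44) and PLAUR (1.25) rose among 20 matrix protease genes and 3 fell. Ligand genes went both ways (4 higher, 6 lower of 22), with HBEGF at 2.33 and STC2 at -1.37. The actin and contractile list had 3 higher and 2 lower of 24 (SMTN, 2.08; LMOD1, -1.32), the amino acid and ATF4 list 3 and 2 of 27 (CHAC1, 1.19; TRIB3, 0.74), the hypoxia list 1 and 3 of 18 (CA12, 1.11; ADM, -1.11), the p53 list 1 and 3 of 16 (FAS, 0.52; DDB2, -1.17), and the clock list 1 and 1 of 13 (BHLHE40, 0.95; BMAL1, -1.02). Among 16 receptor genes NRP1 rose (0.87) and SDC2 (-0.70) and PDGFRA (-0.62) fell, while PDGFRB (-0.47) and FGFR1 (-0.22) did not pass. Another probe set for NRP1 gave 0.40 and did not pass. KRT15 rose at least 2.87-fold and DSP fell (-0.75) among 5 tested keratinocyte markers, and MITF fell (-0.99) among the melanocyte markers.

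In total 1226 genes passed after 24 h of PDGF-BB, 572 higher and 654 lower, and 497 of them changed at least 2-fold. With the replicate block the count was 2107, 1034 higher and 1073 lower, which included the 1226. It was 787 and 517 without control replicates 1 and 2, and 503 without PDGF-BB 24 h replicate 2. The balance of directions depended on the scaling and the arrays, with 473 higher and 802 lower with a common median, and 194 and 309 without PDGF-BB 24 h replicate 2.

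After 24 h of b-FGF, SPC25 rose at least 15.7-fold and NCAPH at least 6.48-fold from background, and CDK1, the kinase of mitotic entry, rose from 20.4 ± 1.81 to 457 ± 228 (SD, n = 2; log2 change 4.26 ± 0.47 SE, adjusted p = 0.000122). HMMR (4.05), PBK (3.90), UBE2C (3.61), KIF4A (3.60), HJURP (3.56), CEP55 (3.48), ZWINT (3.47) and BUB1B (3.43) also rose, together with STC1 (4.16). Of the 40 mitosis genes 38 rose, all 40 when adjusted over the list alone, with a median of 2.73, including TPX2 (2.78), PTTG1 (2.08), KIF20A (2.74) and RACGAP1 (2.80). Of the 40 G1/S and replication genes 29 rose, 33 over the list alone, with a median of 1.46, including RRM2 (2.90), MCM5 (2.14), FEN1 (2.15) and POLE2 (2.27). CCND1 rose by 0.85. Adjusted p was 6.58e-37 and 9.00e-19 with the preset correlation, and adjusted p = 0.115 and 0.120 with an estimated correlation.

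After 24 h of b-FGF, PCDH8, OLFM4 and CDH6 fell at least 13.6-fold, 15.7-fold and 8.06-fold to background, and CPA3 (-3.88), the retinaldehyde dehydrogenase gene ALDH1A1 (-3.57), IFIT1 (-3.43), the endothelin gene EDN1 (-3.43) and RASGRP1 (-3.35) fell. Other probe sets for CDH6 gave smaller log2 changes of -1.95, -2.08 and -0.69, and the last did not pass. EDN1 went from 133 ± 7.81 to 10.8 ± 3.63 (SD, n = 2; adjusted p = 3.36e-05). Of 42 collagen and matrix genes 20 fell, 1 rose and 21 did not pass, with 27 lower and 2 higher when adjusted over the list alone, with a median of -0.43, and those that fell included COL5A2 (-0.68), COL4A1 (-0.81), THBS1 (-0.91) and PCOLCE (-0.69). Of 24 actin and contractile genes 8 fell and 2 rose, 9 and 2 over the list alone, among them LMOD1 (-2.61), ACTA2 (-1.40) and CNN2 (-1.24) against SMTN (2.49). COL1A1 (-0.53), TWIST1 (-1.02) and FBN1 (-0.45) were among 7 of 16 fibroblast markers that fell, with 2 that rose (PRRX1, 1.56), and 10 and 2 over the list alone. The 3 lists had adjusted p = 7.95e-09, 0.0121 and 0.00719 with the preset correlation, and each had adjusted p = 0.115 with an estimated correlation. The fibroblast marker list did not pass after quantile normalization.

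Genes of amino acid synthesis, amino acid transport and the ATF4 response fell with b-FGF at 24 h. Of 27 members 12 fell, 18 when adjusted over the list alone or with the block, with a median of -0.65. The transporter genes SLC7A5 (-1.29) and SLC7A11 (-1.08), the transcription factor gene ATF4 (-0.85) and the asparagine synthetase gene ASNS (-0.79) fell, with ASNS going from 932 ± 19.2 to 540 ± 27.0 (SD, n = 2; adjusted p = 0.000544). Adjusted p was 1.03e-08 with the preset correlation and adjusted p = 0.115 with an estimated correlation.

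FOXO1 fell to 7.85 ± 3.29 with b-FGF (log2 change -1.61 ± 0.31 SE, adjusted p = 0.00507) and FOXO3 fell by 0.69 on the log2 scale (adjusted p = 0.0148), while FOXO4 did not pass (-0.34). The background level on the b-FGF 24 h arrays was 4.14 and 7.17, close to FOXO1. The other FOXO1 probe set gave -1.71 and did not pass. Of the 21 FOXO genes and targets 11 fell, 13 over the list alone, with a median of -0.49, including GABARAPL1 (-2.24), IRS2 (-2.06), MXI1 (-1.29) and CITED2 (-1.02). Lipid genes rose: 10 of 21 in the sterol list, 13 over the list alone (EBP, 1.79; ACAT2, 1.43; INSIG1, 1.00; FDPS, 0.96), and 7 of 14 in the fatty acid list, 8 with 2 lower over the list alone (ELOVL6, 1.99; LPIN1, 1.68; SREBF1, 1.15; ACLY, 0.68). The FOXO, sterol and fatty acid lists had adjusted p = 2.68e-07, 3.56e-08 and 0.00321 with the preset correlation, and adjusted p = 0.115, 0.218 and 0.115 with an estimated correlation.

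Growth factor ligand genes fell more often than they rose after 24 h of b-FGF, with 8 lower and 4 higher of 22 and 10 and 4 over the list alone. FGF2 itself, which encodes b-FGF, fell from 735 ± 245 to 156 ± 7.02 (SD, n = 2; log2 change -2.18 ± 0.22 SE, adjusted p = 7.82e-05), STC2 fell (-2.40), and HGF rose (3.04). Other probe sets for HGF gave 0.98 to 2.49, and those at 0.98 and 1.34 did not pass. ERK feedback had 7 of 16 higher and 1 lower (ETV1, 2.55; SPRY2, 1.42; DUSP6, 1.30; DUSP1, -1.22), TGF-β and BMP response 6 of 22 lower and 1 higher (ID2, -2.32; BAMBI, -1.87; KLF10, -0.83; LTBP1, 1.64), the unfolded protein list 7 of 18 higher and 1 lower (MANF, 1.17; SDF2L1, 1.04), glycolysis 5 of 20 higher, 9 with the block (PFKP, 1.09; PFKFB3, 0.97), quiescence 5 of 17 lower and 1 higher (CDKN1C, -1.83; NUPR1, -1.27), interferon response 4 of 23 lower, 7 with the block (IFIT1; IFIT2, -2.22; IFIT3, -1.41; IFI44L, at least 2.06-fold lower), and p53 targets 3 of 16 lower, 5 with the block (GADD45A, -0.75; PPM1D, -0.75). Over the list alone the higher and lower members numbered 7 and 2, 1 and 6, 8 and 2, 5 and 0, 3 and 6, 0 and 6, and 0 and 3. In the order given, starting with the ligands, these 8 lists passed with the preset correlation but had adjusted p = 0.120, 0.115, 0.115, 0.139, 0.219, 0.219, 0.336 and 0.297 with an estimated correlation.

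Among lists that did not pass with b-FGF at 24 h, PLAU (2.85), MMP1 (1.87) and PLAT (1.53) rose in the matrix protease list, where ADAMTS5 fell (-2.60); HAS2 (3.22) and HMMR rose and ITIH5 fell (-0.72) in the hyaluronan list. PTGS2 (3.07) rose and IL6 (-2.25), CCL2 (-1.73) and NFKBIA (-0.66) fell in the cytokine list. PHLDA1 (2.52) rose and CCN2 (-1.56), ATF3 (-1.60) and GADD45B (-1.28) fell among the immediate early genes, of which 4 rose and 9 fell, 14 with the block. Among receptor genes NRP1 (1.14), SDC1 (0.74) and PDGFRA (0.59) rose, SDC2 (-1.20) and PDGFRB (-0.96) fell, and FGFR1 (-0.22) did not pass. Another probe set for NRP1 gave 0.32 and did not pass. BMAL1 (-1.02) fell and BHLHE40 (0.61) rose among clock genes, ERO1A rose (1.25) and ADM fell (-1.58) among hypoxia genes, KRT15 rose at least 3.37-fold and LAMB3 by 1.15 among keratinocyte markers, and the ribosome biogenesis list had a median of 0.02. FOS (-2.33, adjusted p = 0.0983), EGR1 (-0.26) and MYC (0.24) did not pass.

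In total 1305 genes passed after 24 h of b-FGF, 674 higher and 631 lower, and 616 changed at least 2-fold. With the replicate block the count was 2062, 1063 higher and 999 lower, which included the 1305. It was 640 without control replicate 2 and 648 without b-FGF 24 h replicate 2. Lower genes were in the majority with a common median (633 higher and 671 lower), without b-FGF 24 h replicate 2 (306 and 342), and with the block and quantile normalization (1017 and 1042).

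**Figure D3:**
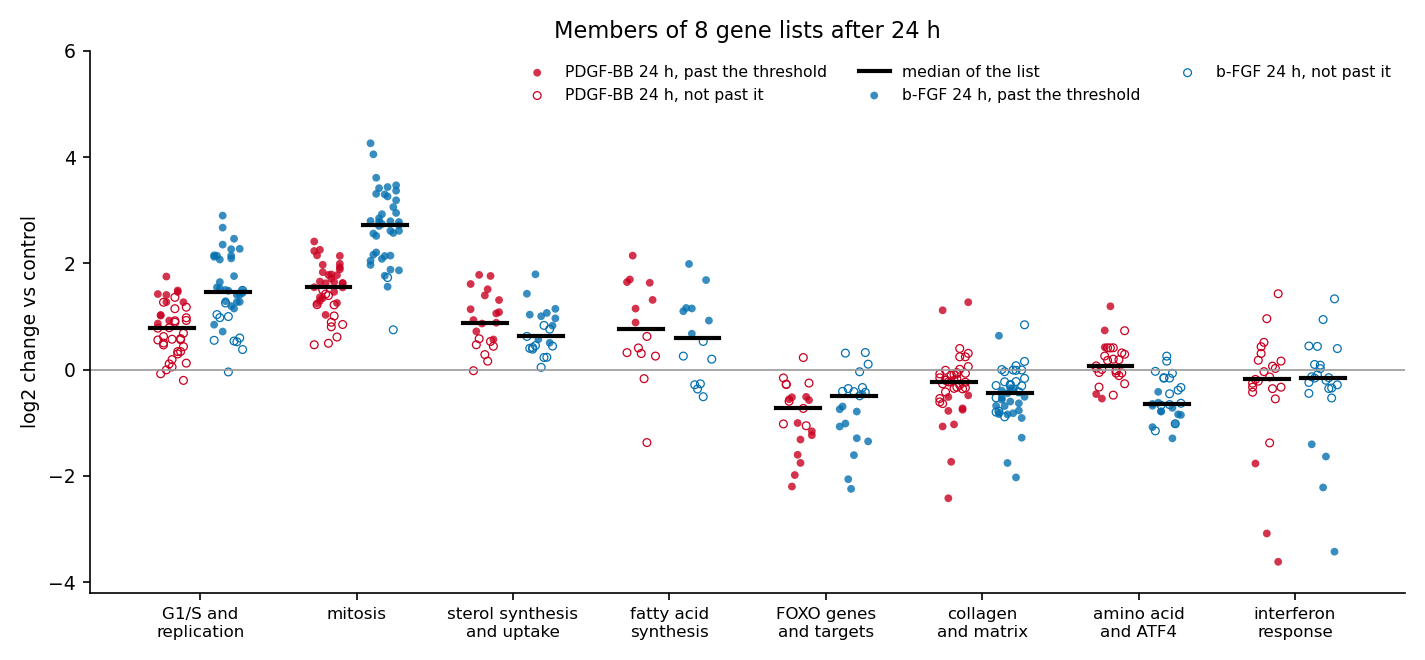
Log2 change against the control after 24 h of PDGF-BB (red) and b-FGF (blue) for the members of 8 gene lists named on the x axis. Each circle is 1 gene fitted from 2 arrays per group, filled where its adjusted p was under 0.05, and black lines mark list medians; the mitosis median is 1.55 with PDGF-BB and 2.73 with b-FGF, and the amino acid and ATF4 median is 0.07 and -0.65.

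The 24 h responses overlapped widely. There were 406 genes higher with both factors, against 45.0 expected of independent lists, and 417 lower with both, against 48.1. Across the 8576 genes, which are not independent replicates, r was 0.794 (Spearman 0.746), where groups without change against the same controls gave 0.499 in simulation, and the covariance was 0.320 against a simulated 0.0515. The controls were not split here either, so part of the excess may come from the shared arrays. Only 3 of the genes called with both factors went in opposite directions: ASNS and TRIB3 rose with PDGF-BB and fell with b-FGF, and the PDGF receptor gene PDGFRA fell with PDGF-BB and rose with b-FGF. PDGFRA stood at 1155 ± 73.4 in the control, 750 ± 74.1 after PDGF-BB and 1770 ± 471 after b-FGF (SD, n = 2). A dimmer probe set for PDGFRA, with a mean signal of 21.2, gave a PDGF-BB change of 0.01. That probe set gave a b-FGF change of 0.31 and a difference between the factors of -0.30, and did not pass in any of these comparisons.

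Compared directly at 24 h, 70 genes differed between the factors, 38 higher and 32 lower with PDGF-BB, and 43 of them by at least 2-fold. FABP3 was higher with PDGF-BB (log2 difference 2.18 ± 0.27 SE, adjusted p = 0.00493), as were the small heat shock protein gene HSPB3 (2.07), the tubulin gene TUBB2B (1.97), the activin subunit gene INHBE (1.79), TRIB3 (1.52), TPD52L1 (1.48), the cystathionine lyase gene CTH (1.47) and PCDH8 (at least 1.39-fold, with b-FGF at background). TM4SF1 (-1.96), NDC80 (-1.65) of the kinetochore, TMEM35A (-1.65), PBK (-1.63), NUSAP1 (-1.52), PKIA (-1.51), BIRC5 (-1.43) and the Wnt inhibitor gene SFRP1 (-1.36) were lower with PDGF-BB. Other probe sets for TM4SF1, NUSAP1, BIRC5 and SFRP1 had the same direction and did not pass. Nor did those for TPD52L1 (1.07) and CTH (1.29). PDGFRA differed by -1.21 (adjusted p = 0.00900).

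Amino acid and ATF4 genes were higher with PDGF-BB than with b-FGF in 9 of 27 cases, 17 with the replicate block, and 19 with 1 lower when adjusted over the list alone. ASNS differed by 1.21 ± 0.11 SE (adjusted p = 0.000810), SLC7A5 by 1.28 and CEBPG by 1.16. The list passed with an estimated correlation (adjusted p = 0.0462) but not when the block was added to it (adjusted p = 0.118). The actin and contractile list was higher with PDGF-BB, with 3 of 24 genes past the threshold, LMOD1 (1.29), ACTA2 (1.04) and CNN1 (0.95), and 6 with the block or over the list alone; its adjusted p = 0.0359 with an estimated correlation became 0.118 with the block. Mitosis genes were lower with PDGF-BB: 8 of 40 passed, 26 with the block and 32 over the list alone, with a median difference of -1.21 that was -1.24 within replicate set 1 and -1.14 within replicate set 2. From the G1/S list PCNA (-0.72) passed, 14 genes with the block and 11 over the list alone. Adjusted p was 8.81e-30 and 3.72e-14 with the preset correlation, and adjusted p = 0.175 and 0.200 with an estimated correlation. Lists of cytokine, ligand, collagen, ribosome biogenesis, fatty acid, immediate early, sterol and unfolded protein genes were higher with PDGF-BB with the preset correlation, with median differences of 0.33, 0.48, 0.19, 0.24, 0.13, 0.20, 0.23 and 0.10. None passed with an estimated correlation (adjusted p = 0.0727, 0.0727, 0.175, 0.175, 0.159, 0.200, 0.691 and 0.248), and over the list alone 4, 2, 10, 1, 2, 2, 0 and 2 members were higher. For the sterol list the direction given by camera turned without b-FGF 24 h replicate 1.

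With the replicate block, 382 genes differed at 24 h, 160 higher and 222 lower with PDGF-BB, which included the 70 and turned the majority, as did a common median (31 higher and 35 lower), a pseudocount at the 40th percentile (35 and 37) or of 32 (40 and 66), and leaving out PDGF-BB 24 h replicate 2 (28 and 31). A fit of only the 4 arrays compared gave 0 genes with limma, 828 at an unadjusted p under 0.05, and a lowest adjusted p of 0.0561. The count was 42 without either control array, 32 and 33 without PDGF-BB 1 h replicates 1 and 2, 38 without either b-FGF 1 h array, 17 without PDGF-BB 24 h replicate 1, and 26 and 27 without b-FGF 24 h replicates 1 and 2.

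**Figure D4:**
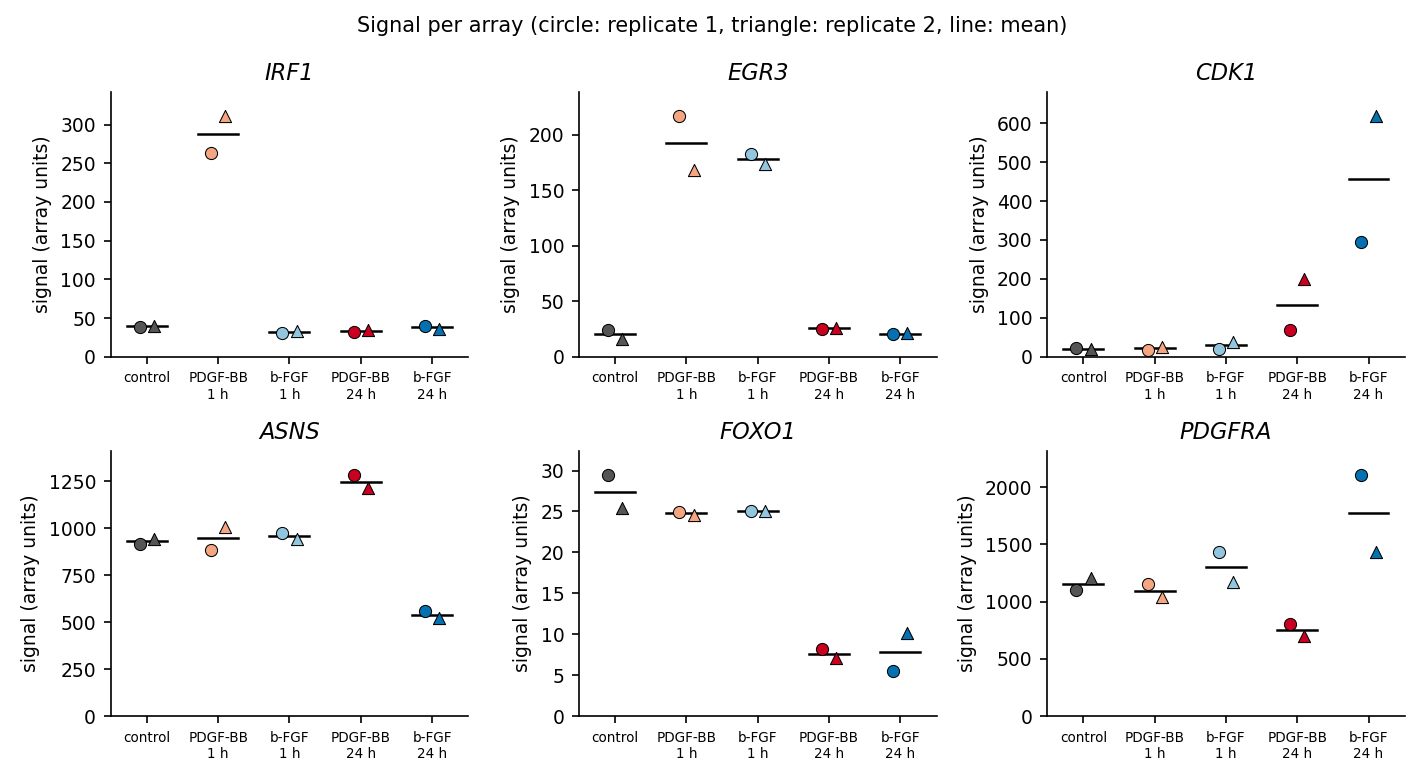
Signal per array, on linear axes that start at 0, of 6 genes in the 5 groups (2 arrays each; circles replicate 1, triangles replicate 2, lines group means). IRF1 is high only on the 2 arrays of PDGF-BB at 1 h, EGR3 is high with both factors at 1 h, CDK1 and PDGFRA are highest with b-FGF at 24 h, ASNS lies above the control with PDGF-BB and below it with b-FGF at 24 h, and FOXO1 is lower with both factors at 24 h.

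Comparison of the times asked how far the early response lasted. Of the 65 genes called with PDGF-BB at 1 h, 40 did not pass against the control at 24 h and 47 were lower at 24 h than at 1 h in the direct test; for b-FGF these numbers were 14 and 20 of 23. Between the times 1276 genes differed for PDGF-BB, 593 higher and 683 lower at 24 h, and 1454 for b-FGF, 759 higher and 695 lower. With PDGF-BB, CISH and the kinase gene MAP3K8 fell at least 13.9-fold and 9.41-fold from 1 h to background at 24 h, SOCS3 (-4.64, and -1.87 by its other probe set) and NR4A1 (-4.00, and -2.87 and 0.02 by dimmer probe sets) fell, FABP3 rose (2.63), and SPC25, MTSS1 and ITPKA rose at least 5.46-fold, 4.79-fold and 2.92-fold from background. With b-FGF, EDN1 fell by 4.97 on the log2 scale, from 400 ± 104 at 1 h (SD, n = 2; adjusted p = 3.77e-06), PCDH8 and CDH6 fell at least 16.6-fold and 9.49-fold, and CPA3 fell (-4.05), while STC1 (4.43), HMMR (4.13), CDK1 (3.85) and TOP2A (3.73) rose. Other probe sets for CDH6 gave log2 changes of -2.25, -2.39 and -0.75 between the times of b-FGF, and the last did not pass. With the block the counts of genes that differed between the times were 2144 and 2192. They were 797 and 604 without PDGF-BB 1 h replicates 1 and 2 and 532 without PDGF-BB 24 h replicate 2, and 808 without b-FGF 1 h replicate 2 and 804 without b-FGF 24 h replicate 2. The majority direction turned for b-FGF with a common median (641 higher and 789 lower) and without b-FGF 24 h replicate 2 (388 and 416), and for PDGF-BB with the block and quantile normalization (1116 and 1086).

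The difference between the factors itself changed with time for 18 genes in the test of the factor by time interaction, 9 in each direction. Relative to b-FGF, PDGF-BB values moved down from 1 h to 24 h for IRF1 (-3.27 ± 0.25 SE, adjusted p = 0.000323), and up for HSPB3 (2.38 ± 0.28 SE, adjusted p = 0.00960) and ASNS (1.23 ± 0.15 SE, adjusted p = 0.0112). The replicate block gave 110 genes, 43 up and 67 down, which included the 18. The count was 11 without either control array or without PDGF-BB 24 h replicate 2, 8 without b-FGF 24 h replicate 1, 4 without PDGF-BB 1 h replicate 2 or b-FGF 24 h replicate 2, 2 without PDGF-BB 24 h replicate 1, and 1 without PDGF-BB 1 h replicate 1 or either b-FGF 1 h array.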

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

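All tests of explanations in this part were chosen after the results were seen. A difference between the factors that was not the same at 24 h as at 1 h, by the test of the interaction, set the following results apart: 18 genes, of which 16 are given here as the log2 difference between PDGF-BB and b-FGF at 24 h less that at 1 h. It was above 0 for TUBB2B (2.42), HSPB3 (2.38), TRIB3 (1.48), TPD52L1 (1.33), INHBB (1.30), SLC7A5 (1.27), ASNS (1.23) and MEST (1.13), and below 0 for CISH (-6.03), TM4SF1 (-3.49), IRF1 (-3.27), STC1 (-2.54), ID3 (-2.18), ID1 (-1.85), NFIL3 (-1.72) and BHLHE40 (-1.62). CISH was at background after 24 h of PDGF-BB (mean signal 1.24), so its value depends on the pseudocount and is not a measured size.

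The same test set 11 gene lists apart, with the preset correlation only. The median of this difference was -0.69 for G1/S and replication, -1.33 for mitosis, 0.13 for sterol synthesis, 0.20 for fatty acid synthesis, 0.15 for collagen and matrix, 0.17 for contractile genes, -0.34 for TGF-β and BMP response, 0.11 for ribosome biogenesis, 0.70 for amino acid and ATF4 genes, 0.16 for the unfolded protein list and -0.25 for interferon response. With an estimated correlation their adjusted p was 0.106 to 0.607.

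The first pattern weighed was the 8 genes higher with PDGF-BB than with b-FGF at 1 h. A b-FGF response weaker by 1 common factor is argued against for 1 of them, IRF1. The factor was fitted without the 8 genes and was 0.65 times the PDGF-BB change over 57 genes called with PDGF-BB, and 0.73 over 42 genes called on the mean of both factors. With departures adjusted over all 8576 genes, IRF1 departed from both (adjusted p = 0.00117 and 0.000360). For the other 7 a weaker response stays open: BHLHE40 and ID1 departed from the second factor only (adjusted p = 0.144 and 0.0224 for each), NFIL3, ID3, ATF3 and CCNL1 from neither, and CISH had its control at background. A fit that included the 8 genes, over the 65 genes called with PDGF-BB (factor 0.53), had 17 departures at an adjusted p under 0.05 over those 65, 11 above and 6 below. The 6 were IRF1, CISH, BHLHE40, ID1, NFIL3 and PLK2. By this fit the 65 did not all follow 1 factor, but genes chosen for their PDGF-BB change do not exclude it for the other 7. A list of 22 other STAT target genes had a median difference of 0.29 at 1 h (camera p = 2.22e-08, p = 0.00459 with an estimated correlation; 19 of 22 above 0, 0 past the threshold and 4 with the replicate block), which is consistent with a stronger STAT response to PDGF-BB as a hypothesis, and also with a weaker b-FGF response in general, since the immediate early list differed by 0.37. Heparin in the b-FGF medium stays open, since 0 arrays received it without b-FGF.

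The second pattern was the amino acid and ATF4 list, lower with b-FGF than with PDGF-BB at 24 h (adjusted p = 0.0462 with an estimated correlation, 0.118 with the block added). Scaling of the arrays is argued against, since the median difference was 0.69 after quantile normalization and 0.70 as deposited, with 23 of 27 members above 0 in both replicate sets. More dividing cells in the b-FGF cultures stays open. Mitosis genes differed between replicate sets by 0.57 more at 24 h than in the other groups. There the list differed by -0.16, against -0.33 expected if division alone set it. The SE of that -0.16, 0.0348, came from resampling the list's genes and does not measure the spread between arrays. After 24 h of PDGF-BB the mitosis median was 1.55 and that of this list 0.07 (quartiles -0.06 and 0.36), so division alone does not give the changes from the control; a rise shared by both factors beside it was not tested. Heparin stays open too, with 0 arrays given it alone, though the list had a median change of 0.03 and 0 genes past the threshold after 1 h of b-FGF with heparin.

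The third pattern was the mitosis list, higher with b-FGF than with PDGF-BB at 24 h by the preset correlation and not by an estimated one (adjusted p = 0.175). A difference between the replicate sets is argued against, since 39 of 40 members were higher with b-FGF within both sets. Independent noise of signals near background is argued against by the same 39 of 40 members. A shift shared by dim signals stays open. The 5 members with a signal of at least 100 on both PDGF-BB 24 h arrays had a median difference of -0.91 beside -1.21 for the list. They were too few to decide, and 4 of them were lower with PDGF-BB. The SE of their median, 0.295, came from resampling these genes and does not measure the spread between arrays. A condition written before the result asked that all 12 members with a mean signal of at least 100 be lower with PDGF-BB; it was not met, by AURKA, and 8 of the 12 reached 100 only through the b-FGF 24 h arrays. Independent noise would not put 39 of 40 members on 1 side, but a shift shared by dim signals was not tested. A stronger mitotic response to b-FGF with heparin stays open too, as other doses were not there to test it.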

How the results depend on the processing

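The pseudocount of 32, alone or with the block, and the block with quantile normalization were added after results were seen. Among named genes 8379 values stayed on their side of the threshold under the alternatives, 943 no longer passed, 6 newly passed and 0 reversed. A change of direction was counted only where the main fit or the alternative passed. Only lists that passed in the main fit were followed, so none could newly pass. Of their values 2562 stayed, 218 no longer passed and 2 reversed. Without b-FGF 24 h replicate 1 the direction given by camera turned for the sterol list (adjusted p = 0.753 and 0.775), where its median was 0.0030 between the factors at 24 h, still above 0, and -0.0458 for the interaction; leaving out each array gave 0.0030 to 0.47 and -0.0458 to 0.38. Of the counts and correlations 158 stayed and 93 moved; the cause was not tested, except that smaller fits and filters change the number of arrays or genes tested. Counts follow in the order PDGF-BB 1 h, b-FGF 1 h, PDGF-BB 24 h and b-FGF 24 h against the control, the factors at 1 h, the factors at 24 h, the times for PDGF-BB, the times for b-FGF, and the interaction. With the replicate block they were 103, 39, 2107, 2062, 34, 382, 2144, 2192 and 110, and no call was lost; with the block and a pseudocount of 32 they were 111, 41, 2118, 2097, 49, 437, 2176, 2202 and 145, and with the block and quantile normalization 99, 40, 2134, 2059, 35, 384, 2202, 2191 and 100. Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 31 to 70, 2 to 25, 503 to 1234, 640 to 1280, 4 to 10, 17 to 59, 532 to 1245, 804 to 1425 and 1 to 11.

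Without a variance trend, 32 genes passed for PDGF-BB at 1 h, 7 for b-FGF at 1 h, 16 between the factors at 24 h and 2 for the interaction. Fits of only the groups compared gave 10 for b-FGF at 1 h, 16 between the factors at 1 h, 0 between them at 24 h and 11 for the interaction. A minimum fold of 2 left 497 and 616 at 24 h against the control, 43 between the factors at 24 h, and 505 and 700 between the times. Between the factors at 1 h there were 4 with a common median, 5 each with no pseudocount, no filter, a filter at the 60th percentile or probe sets tested singly, and 17 with a pseudocount of 32. Between them at 24 h there were 34 with no filter, 32 with probe sets tested singly and 106 with a pseudocount of 32, and for the interaction 7 with no filter, 7 with probe sets averaged and 6 with them tested singly. The correlation of the 24 h changes was 0.757 with no pseudocount. Signal over background limits changes of dim genes: the median signal was 17.7 to 19.8 per array, and the background level 3.98 to 7.66.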

Other observations

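The tests of retinoid and Wnt genes in this part were chosen after values of some members were seen, and the genes named were chosen for their values. Some early genes kept their direction to 24 h and others turned. With PDGF-BB, HBEGF (log2 change 2.25 at 1 h and 2.33 at 24 h), PHLDA1 (1.89 and 2.09), PMAIP1 (1.32 and 1.86) and the phosphate transporter gene SLC20A1 (0.76 and 1.91) were higher at both times, while CEBPD (1.33 and -1.90), ID3 (2.74 and -0.85), SGK1 (1.22 and -1.54) and GADD45B (1.41 and -0.91) were higher at 1 h and lower at 24 h. With b-FGF, DUSP5, FOSL1, PHLDA1 and SPRY2 were higher at both times, and ATF3 (2.20 and -1.60), NR4A1 (2.04 and -1.34), IER3 (1.62 and -0.83), DUSP1 (1.11 and -1.22) and SGK1 (0.92 and -1.06) turned. Between 1 h and 24 h the changes correlated across genes at 0.244 for PDGF-BB, with 18 genes higher at both times against 4.27 expected of independent lists, and at 0.146 for b-FGF, with 4 against 1.81; groups without change against the same controls gave 0.499, and part of these overlaps may come from the shared controls. With no pseudocount the correlations were 0.279 and 0.205.

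A hypothesis from the decrease of ALDH1A1 (-2.91 with PDGF-BB and -3.57 with b-FGF at 24 h) was that retinoid metabolism genes are lower at 24 h. DHRS3 (-2.27 and -2.81) and RXRA (-0.99 and -1.01) fell, RDH11 rose (0.97 and 1.23), and CRABP2 rose with PDGF-BB (0.82), did not pass with b-FGF (-0.13), and differed between the factors (0.95, adjusted p = 0.00591). Over 10 tested genes the median change was -0.48 with PDGF-BB (camera p = 0.101) and -0.42 with b-FGF (camera p = 0.0222, and p = 0.0655 with an estimated correlation). Members went in both directions, so the test left the hypothesis undecided. ALDH1A1, which prompted it, was not taken out for the test.

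A further hypothesis was that Wnt ligands, receptors and inhibitors differ between the factors at 24 h. Of 20 tested genes, 5 fell with PDGF-BB and 6 fell and 2 rose with b-FGF; WNT2 (-2.67 and -3.12), FZD2 (-1.14 and -0.78), FZD7 (-0.82 and -0.65) and DKK1 (-0.87 and -0.69) fell with both, and FZD1 (1.48) and SFRP1 (1.59) rose with b-FGF. The median difference between the factors was -0.14. The list passed at the preset correlation (camera p = 0.0306) and not at an estimated one (camera p = 0.205). Only SFRP1 passed by itself, and its other probe sets, at -0.93 and -1.24, did not. SFRP1 was already among the largest differences between the factors, and the list was not tested without it.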
